A study of Mus musculus with 12 samples.

How the data were processed

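Liver RNA had been extracted with TRIzol from frozen tissue and made into libraries with the NEBNext Ultra RNA kit for Illumina, per the labels' protocols. This kit does not mark the strand, and the strand setting used in counting is not given in the sources used here, so reads from a gene and an overlapping or antisense partner cannot be told apart. The deposited table held raw read counts per gene for all 12 libraries, whole numbers with different totals per library. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build mm39. The gene IDs, however, are those of a strain annotation for C57BL/6NJ (41096 IDs that start with MGP_C57BL6NJ), which is not the reference annotation of mm39, so the build behind the counts is uncertain and no coordinates are given. A further 1458 rows are unannotated loci. How reads shared between near-identical genes were counted is not given in the sources used here, and families of such genes are therefore uncertain.

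Libraries were grouped by the genotype and diet in the labels into WT ND, KO ND, WT HFD and KO HFD, with 3 replicates each. Nothing in the labels ties a replicate to a separate animal beyond its being a separate sample, so p-values measure the spread between these samples, which may be technical in part. No pair of replicates was a duplicate: the chi-square per degree of freedom between replicates of a group was 8.05 to 165, where sampling noise alone gives about 1.

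Total counts per library were 13339879 to 15933886. A count of 0 allows up to 3 counts per library, which was used as the floor, and ratios of low counts are given with 95% exact binomial intervals. Shares of counts in single libraries have 95% Wilson intervals. In all, 18703 rows had no count in any library. Genes were kept by filterByExpr in edgeR with the 4 groups, which left 13843 genes that held 99.9% of the counts in each library.

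Counts were normalised with trimmed mean of M-values (TMM) factors and tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust, R 4.3.3) in one model with a mean per group over all 12 libraries. There were 6 comparisons: KO against WT on HFD and on ND, HFD against ND in WT and in KO, the diet by genotype interaction, and KO against WT averaged over diets. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and fold changes are log2 with their standard errors. Normalised CPM used TMM library sizes, and log CPM a prior count of 2. Single values per library were compared with two-sided exact permutation tests over all splits of 3 against 3. The tests, the comparisons and the first set of alternative settings were fixed before the data were examined.

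Each library was also given a diet score and a genotype score by projecting its log CPM on the difference of 2 group means, over the genes called between WT ND and WT HFD or between WT ND and KO ND. A library was scored on directions fitted without it or, for groups outside the direction, on the mean of 3 directions that each left out 1 library. For the genotype score these left out a KO ND library for KO HFD and a WT ND library for WT HFD. The 2 HFD groups were therefore scored on different directions. Both scores were defined after the data had been seen, and then revised. In the first form the gene with 0 counts in every KO library was kept. For the diet score, KO libraries were scored in that form on directions fitted from more WT libraries than WT libraries were. For the genotype score, KO HFD and WT HFD libraries were both scored in that form on directions fitted from all ND libraries. That form gave a difference between KO HFD and WT HFD of -0.135 for the diet score (exact permutation p = 0.5) and of 0.179 for the genotype score (exact permutation p = 0.1, the smallest possible).

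The rule for naming genes, fixed in advance, named Nlrp6 first, then 10 genes of lipid handling and inflammasome signalling, then the genes with the largest changes that passed the test with non-overlapping groups, a mean of at least 1 CPM and a symbol. It also covered 38 lists of genes for pathways and cell types. None of the IDs was paired with a symbol in the count table or the gene tables used here (0 matches), so the lists and the named genes were not analysed here. In their place 4 genes are printed by ID, the 2 largest rises and 2 largest falls among annotated genes called between KO and WT on HFD, with non-overlapping groups and a mean of at least 1 CPM.

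The steps were tested on simulated counts with the real library sizes, and with 1 mean and 1 dispersion per gene shared by all groups. Genes were drawn independently, with no diet effect and no larger spread in KO HFD. The real KO HFD group had a larger spread than the others, so the rates below may not hold for comparisons that use it. For KO against WT on HFD, 50.0% of 98 genes changed by a log2 fold of 1 and 81.8% of 99 genes changed by 2 were called, with 5.11% of calls false. The interaction recovered 20.2% and 72.0% of genes at those sizes, and the average over diets 73.7% and 96.9%.

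Alternatives were DESeq2 size factors, no filter or a stricter filter on low counts (1 CPM in 3 libraries), the Wald test of DESeq2 1.42.0, limma-voom (limma 3.58.1), a replicate block, a 2-fold minimum, the 6 libraries of a comparison alone, and each replicate left out in turn. Alternatives added after seeing the data were the 10 most abundant genes left out, the unannotated loci left out, limma-voom with quality weights per library, and the first form of both scores, with and without the gene absent from KO. Figures were drawn with matplotlib 3.10.9.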

Results

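Liver RNA was sequenced from wild-type mice (WT) and from mice lacking NLRP6 (KO), a NOD-like receptor with known roles in inflammasome signalling. Each genotype was studied on a normal diet (ND) and on a high-fat diet (HFD) given for 12 weeks from 8 weeks of age, with 3 libraries in each of the 4 groups. The stated purpose concerns the part NLRP6 plays in fat accumulation within hepatocytes. Total counts ranged from 13339879 in KO HFD replicate 1 to 15933886 in KO ND replicate 1. No difference in total counts between groups passed an exact permutation test (two-sided; lowest p = 0.2, for HFD against ND in KO), in which 3 libraries against 3 allow no p below 0.1. Of 42554 rows in the count table, 13843 had enough counts to be tested and are called genes here, 13291 of them annotated genes and 552 unannotated loci. The gene IDs were not matched to symbols, so the level of Nlrp6 and of lipid, inflammasome and cell type markers was not analysed here. Gene groups are therefore described by how they responded to diet and genotype, and 4 genes are given by ID, chosen after their values were seen.

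One gene followed the genotype label in every library. MGP_C57BL6NJ_G0033694 had 2019 to 2358 counts in the WT ND libraries and 2198 to 2981 in the WT HFD libraries, and 0 counts in all 6 KO libraries. Its mean in WT was 135 ± 10.7 CPM (read counts scaled to a common library size) on ND (SD, n = 3) and 202 ± 38.6 CPM on HFD (SD, n = 3). Against a floor of 3 counts per library, its level in KO was at least 686-fold lower on ND and at least 798-fold lower on HFD. Within WT it was higher on HFD (log2 fold change 0.59, SE 0.16, edgeR quasi-likelihood adjusted p = 0.0139). It was the only gene with at least 5 counts in every library of one genotype and 0 in every library of the other, and no gene separated the diets in this way. Floors and the intervals of count ratios and shares cover counting error only.

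**Figure D1:**
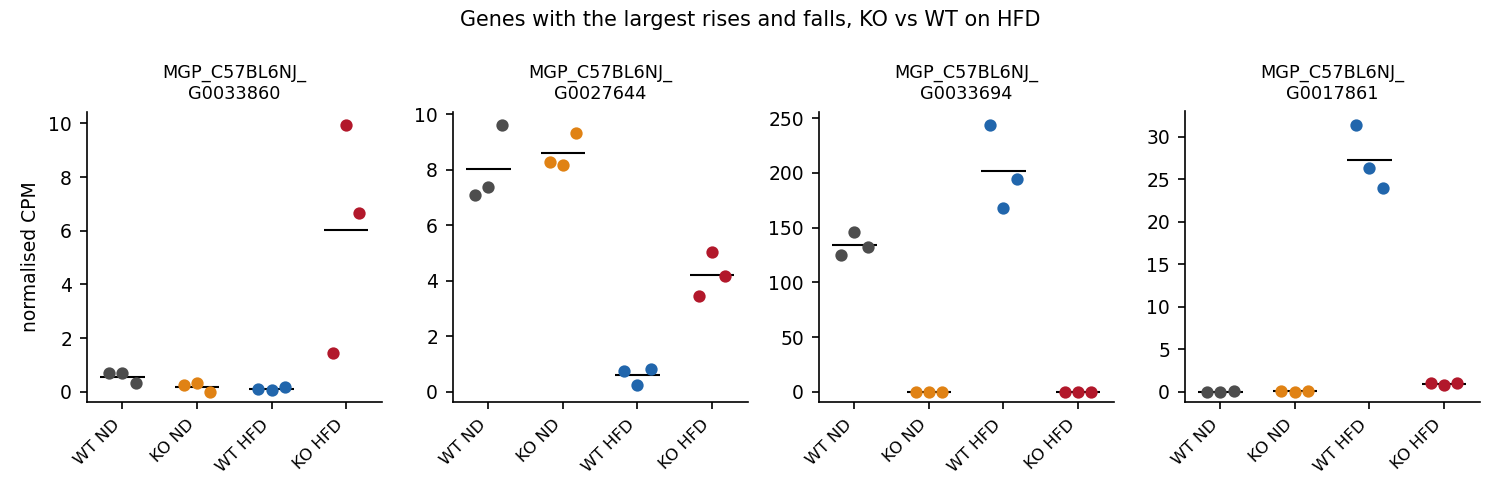
Normalised CPM (linear axes, one scale per panel) of the 2 genes with the largest rises and the 2 with the largest falls in KO against WT on HFD; points are libraries, 3 per group in replicate order, and lines are group means. MGP_C57BL6NJ_G0033694 lies at 0 in all 6 KO libraries, and MGP_C57BL6NJ_G0017861 is high in the 3 WT HFD libraries and averages 0.923 CPM in KO HFD.

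The high-fat diet changed a large part of the WT liver transcriptome. In WT, 2704 genes were higher and 2972 lower on HFD than on ND, 41.0% of those tested, with a median absolute log2 fold change of 0.90. Changes of at least 2-fold were found for 1047 genes that rose and 1436 that fell. Genes that rose in WT held 33.3% ± 2.13 of all counts in WT ND and 52.4% ± 2.04 in WT HFD (SD, n = 3 each), while genes that fell dropped from 18.5% ± 0.781 to 8.29% ± 0.777. MGP_C57BL6NJ_G0017861 was nearly silent on ND, with 0 or 1 count per WT library, and had 296 to 384 counts per WT HFD library, a ratio of 1296-fold with a 95% exact binomial interval from 232 to 51230. MGP_C57BL6NJ_G0027644 fell from 8.03 ± 1.39 CPM to 0.592 ± 0.316 CPM (SD, n = 3 each; log2 fold change -3.76, SE 0.33, edgeR adjusted p = 7.69e-06). The called share rose with abundance, from 18.3% of genes under 1 CPM to 48.5% of those over 100 CPM. Leaving out any 1 of the 6 libraries gave 4380 to 5319 called genes.

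The KO liver responded to the diet as broadly. In KO, 3129 genes were higher and 3066 lower on HFD, 44.8% of those tested, and the median absolute log2 fold change of called genes was 0.91. Of the 5676 genes called in WT, 93.1% moved in the same direction in KO and 3877 were also called there, 1859 higher and 2018 lower, while 52 were called in the opposite direction. Independent lists of these sizes would share 611 higher and 658 lower genes. The 2 responses use no library in common, and across the 13843 genes their log2 fold changes had a Pearson correlation of 0.667 and a Spearman correlation of 0.701, a description across genes, which are not independent replicates. Genes called in both genotypes in the same direction and changed at least 4-fold in both numbered 57 higher and 162 lower. MGP_C57BL6NJ_G0017861 rose on HFD in KO as well, from 3 counts over the 3 ND libraries to 36 over the 3 HFD libraries, a ratio of 15.0-fold with a 95% exact binomial interval from 4.73 to 76.0. Leaving out any 1 of the 6 libraries gave 5045 to 6251 called genes.

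**Figure D2:**
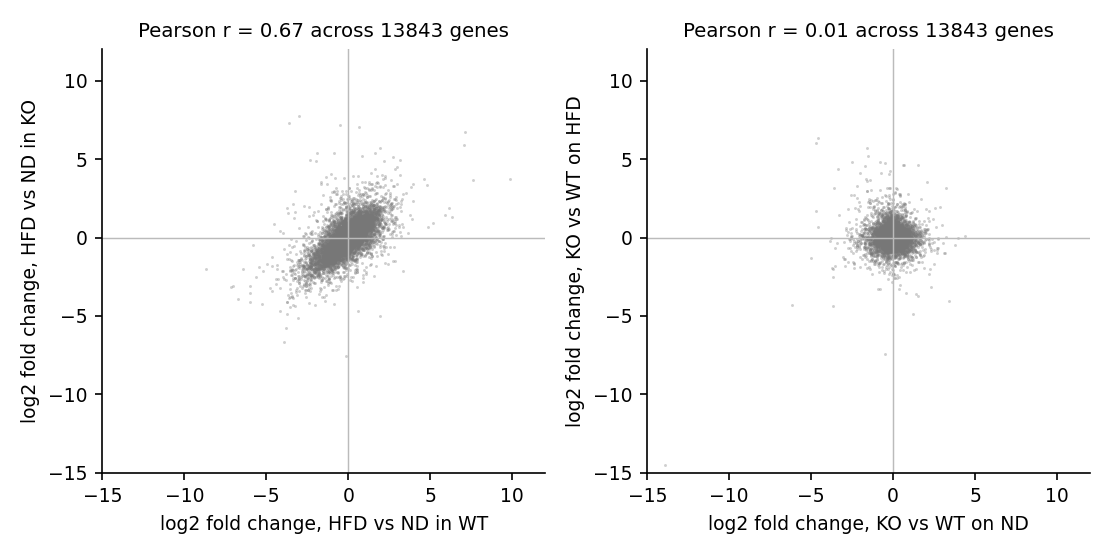
Log2 fold changes of the 13843 tested genes, with the diet response in WT against that in KO on the left and the genotype difference on ND against that on HFD on the right; each point is a gene. The diet responses spread along the diagonal (Pearson 0.667), and the genotype differences do not (Pearson 0.0113). The point at the lower left edge of the right panel is the gene with 0 counts in every KO library, whose fitted fold changes are not bounds. Without it the Pearson correlation of the genotype differences was -0.0387.

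Replicates within the KO HFD group differed more than in the other groups. A diet score was computed for each library over the genes called between diets in WT, on a scale where 0 is the WT ND mean and 1 the WT HFD mean. WT HFD libraries scored 0.903 ± 0.0590 and KO HFD libraries 0.748 ± 0.220 (SD, n = 3 each), a difference within the replicate spread (exact permutation test, two-sided, p = 0.4, where 0.1 is the smallest possible). KO HFD replicate 1 scored 0.982, above all 3 WT HFD libraries, and replicates 2 and 3 scored 0.546 and 0.717, below all 3. Genes that rose on HFD in WT held 54.3% of the counts in KO HFD replicate 1, 36.9% in replicate 2 and 42.7% in replicate 3, each with a 95% Wilson interval of less than 0.03 percentage points to either side, which covers counting error only and not the variation between samples. The biological coefficient of variation was 0.259 in KO HFD, 0.188 in WT HFD, 0.194 in WT ND and 0.162 in KO ND. With 1 library left out it ran from 0.141 to 0.349 in KO HFD and from 0.117 to 0.258 in WT HFD. It ran from 0.135 to 0.225 in WT ND and from 0.142 to 0.189 in KO ND. The lowest values in KO HFD, WT HFD and WT ND each came without replicate 1, so such a fall was not particular to KO HFD. The most abundant gene took 8.97% ± 0.576 of the counts in WT HFD and 5.75% ± 1.56 in KO HFD (SD, n = 3 each; exact permutation test, two-sided, p = 0.1, the smallest possible).

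**Figure D3:**
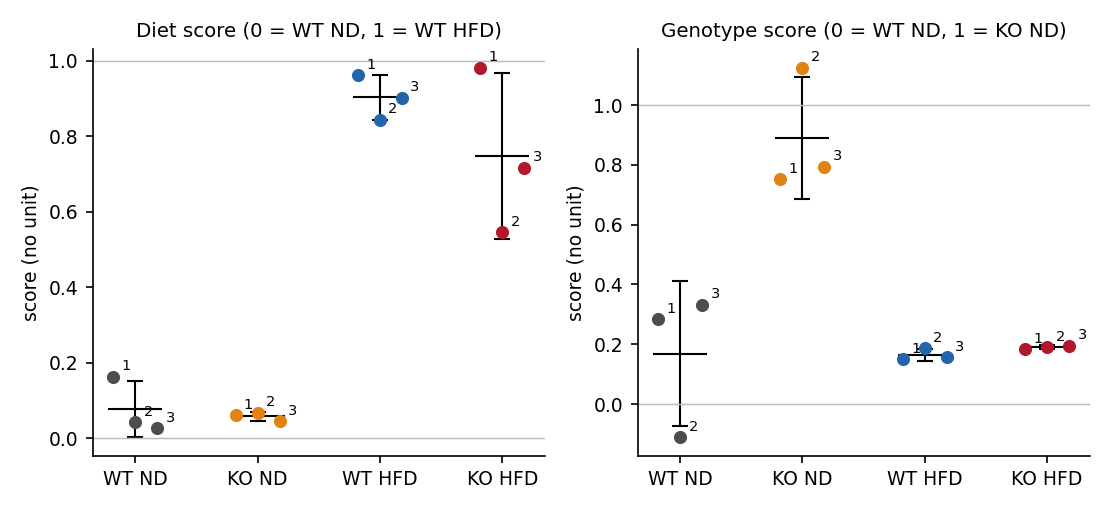
Diet score (left) and genotype score (right) of each library, without unit; points are libraries with their replicate numbers, and bars give the group mean and SD (n = 3). KO HFD replicate 1 lies at 0.982 on the diet score and replicates 2 and 3 at 0.546 and 0.717; on the genotype score all 6 HFD libraries lie between 0.149 and 0.195.

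The comparison of KO with WT on HFD bears most directly on the stated purpose. On HFD, 12 genes were higher and 22 lower in KO, with a median absolute log2 fold change of 1.53, and 12 of the higher and 17 of the lower genes changed at least 2-fold. In all 34 the values of the 2 groups did not overlap. They were called from the same libraries, so this adds no separate evidence. MGP_C57BL6NJ_G0017861, which rose strongly on HFD in WT, averaged 27.3 ± 3.82 CPM in WT HFD and 0.923 ± 0.147 CPM in KO HFD (SD, n = 3 each), 29.5-fold lower with a 95% exact binomial interval from 21.2 to 42.4 (log2 fold change -4.87, SE 0.30, edgeR adjusted p = 1.66e-06). MGP_C57BL6NJ_G0027644, which fell on HFD in WT, averaged 4.22 ± 0.796 CPM in KO HFD against 0.592 ± 0.316 CPM in WT HFD (SD, n = 3 each; log2 fold change 2.83, SE 0.34, edgeR adjusted p = 0.00337). MGP_C57BL6NJ_G0033860 had 17 to 132 counts per KO HFD library and 4 counts over all 3 WT HFD libraries, a ratio of 58.3-fold with a 95% exact binomial interval from 22.5 to 216 (edgeR adjusted p = 0.0135). Under 7 of its 16 alternative settings it was no longer called, with adjusted p from 9.22e-07 to 0.218, while its log2 fold change stayed between 5.08 and 6.18 over all 16 (5.72 as fitted above). MGP_C57BL6NJ_G0027644 was lost only when the 6 HFD libraries were fitted alone, with a log2 fold change of 2.82 (edgeR adjusted p = 0.0857, the highest of a range from 3.27e-10). The number and balance of called genes depended on single libraries: 474 higher and 348 lower, 822 in all, without KO HFD replicate 1, which included all 34, but 12 without KO HFD replicate 2, 7 without KO HFD replicate 3 and 12 without WT HFD replicate 3. A fit of the 6 HFD libraries alone called 8 genes, omitting the low-count filter 71, and DESeq2 261 (136 higher and 125 lower).

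**Figure D4:**
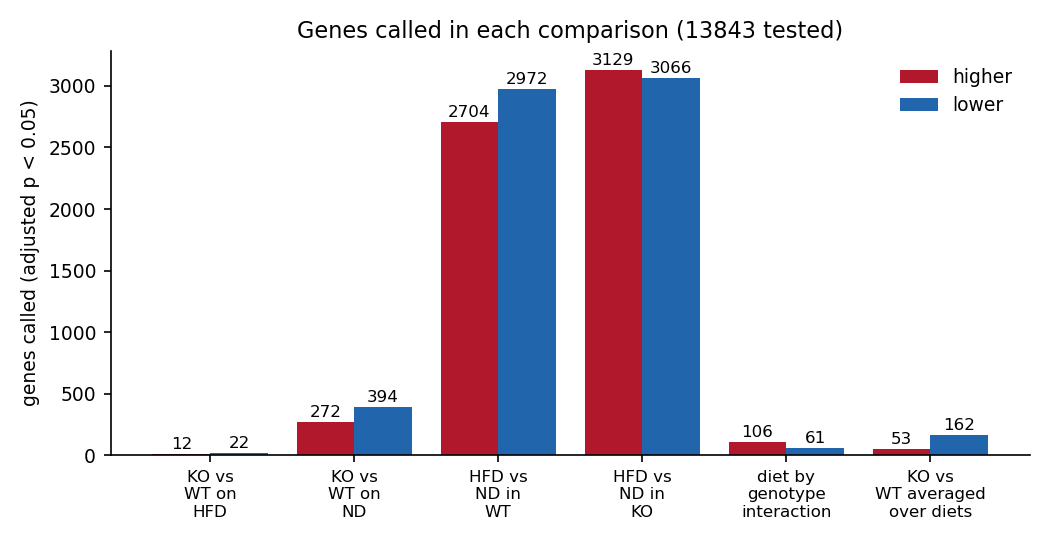
Number of genes called higher (red) or lower (blue) in each comparison among 13843 tested (edgeR quasi-likelihood test, 12 libraries); for the interaction, higher means a KO diet response above that of WT. The 2 diet comparisons call 5676 and 6195 genes, and the genotype comparisons 34 on HFD and 666 on ND.

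On the normal diet the genotypes differed in more genes. KO had 272 genes higher and 394 lower than WT, 4.81% of those tested, with a median absolute log2 fold change of 0.86, and 76 of the higher and 177 of the lower genes changed at least 2-fold. Most of these genes were not called on HFD, and 54.7% had the same sign there, with a median log2 fold change of 0.00 for those higher in KO on ND and -0.05 for those lower. On HFD, 7 were called in the same direction, all lower, and 3 in the opposite one, where independent lists would share 0.236 higher and 0.626 lower genes. Across all tested genes the genotype differences on the 2 diets had a Pearson correlation of 0.0113 and a Spearman correlation of 0.00379, and a Pearson correlation of 0.0887 over genes with a mean of at least 10 CPM. The gene absent from KO alone set the sign of the first value, which was -0.0387 without it. On a genotype score over the genes called on ND, where 0 is the WT ND mean and 1 the KO ND mean, KO ND libraries scored 0.891 ± 0.204 and WT ND libraries 0.169 ± 0.243, while KO HFD and WT HFD libraries scored 0.190 ± 0.00569 and 0.164 ± 0.0195 (SD, n = 3 each; exact permutation test on HFD, two-sided, p = 0.2). Here KO HFD and WT HFD libraries were scored on different directions, fitted with a KO ND or a WT ND library left out. The score was revised after the data were seen. In its first form HFD libraries used directions fitted from all ND libraries. The difference on HFD was then 0.179 (exact permutation p = 0.1, the smallest possible) and that on ND 0.746. Without the gene absent from KO, the first form gave 0.0781 on HFD (exact permutation p = 0.1) and 0.722 on ND. The count on ND fell to 420 without WT ND replicate 1, 119 without WT ND replicate 2, 334 without KO ND replicate 1, 92 without KO ND replicate 2 and 255 without KO ND replicate 3, and was 460 without WT ND replicate 3. DESeq2 called 1313 genes.

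The interaction asked which genes responded to the diet differently in the 2 genotypes. The response was higher in KO than in WT for 106 genes and lower for 61, with a median absolute log2 difference of 1.60. Of the 106, 28 were called lower on HFD in WT and higher in KO, 56 were called higher in KO only, and 13 were called lower in WT only. Of the 61, 13 were called higher in WT and lower in KO, 24 were called lower in KO only, and 14 were called higher in WT only. Most of these genes differed between genotypes on ND: 112 were among the 666 called there. The interaction contains the ND difference from the same libraries, so this overlap is built in to a large part and is no separate evidence. MGP_C57BL6NJ_G0017861 was induced on HFD in both genotypes, and its induction was lower in KO by a fitted log2 difference of -6.11 (SE 1.32, edgeR adjusted p = 0.0401), a value that rests on 1 count in WT ND and 3 in KO ND. MGP_C57BL6NJ_G0027644 fell on HFD in both, and less in KO, by a log2 difference of 2.74 (SE 0.42, edgeR adjusted p = 0.0138). The interaction count was 942 without KO HFD replicate 1 and included all 167, whereas it was 11 without WT HFD replicate 3, 18 without KO HFD replicate 3, 78 without WT HFD replicate 2, 80 without KO HFD replicate 2, 57 without WT ND replicate 2, 95 without WT ND replicate 3, 99 without KO ND replicate 1, 55 without KO ND replicate 2 and 88 without KO ND replicate 3. DESeq2 called 656 genes.

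Averaged over both diets, KO had 53 genes higher and 162 lower than WT, with a median absolute log2 fold change of 0.75, and 10 of the higher and 59 of the lower genes changed at least 2-fold. MGP_C57BL6NJ_G0027644 was among the genes higher in KO on average (log2 fold change 1.46, SE 0.21, edgeR adjusted p = 0.00496), with a genotype difference of 0.10 on ND that was not called. The balance of directions depended on the fit, with 450 higher and 610 lower without KO HFD replicate 1, 226 and 406 with DESeq2, and 1805 and 1694 in limma-voom with quality weights. The count was 1060 without KO HFD replicate 1, and 62 without KO HFD replicate 3, 68 without WT HFD replicate 3, 78 without WT ND replicate 2, 79 without KO ND replicate 2, 110 without KO ND replicate 3, 112 without KO HFD replicate 2, 129 without KO ND replicate 1 and 142 without WT HFD replicate 2. DESeq2 called 632 genes.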

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

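The split tests in this part were set before their results were seen, and the 3 genes were chosen after their values were seen. The diet response differed between genotypes for 167 genes by the interaction term of edgeR. Of 100 splits that exchanged genotype labels within each diet, 2 gave at least as many, the real one included, so a chance division of both diets' libraries together is excluded at that share. That share rests mainly on the ND labels: of the 8 drawn splits that kept the ND groups, the real one included, 2 reached the real count and the other 6 gave 0 to 111, while no split that broke up the ND groups gave more than 4. These splits therefore say little on the HFD labels. The highest other count was 601, from a split that kept the ND groups and exchanged WT HFD replicate 2 with KO HFD replicate 1. A split that calls several times the real number can point to a structure among the HFD samples that does not follow the genotype labels. On HFD alone, however, the same exchange called 8 genes, against 34 for the real labels. For the average over diets, 2 of 100 splits reached the 215 genes of the real labels, the real one included. The highest other count was 370, from the same exchange, against at most 33 where the ND groups were broken up. Leaving out KO HFD replicate 1 gave 942 interaction genes, and leaving out WT HFD replicate 3 gave 11.

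Of the genes printed by ID, 3 passed the interaction test. MGP_C57BL6NJ_G0033860 rose on HFD in KO (log2 fold change 4.96, SE 0.77, edgeR adjusted p = 0.000261) and was not called in WT (-2.32, SE 1.04, edgeR adjusted p = 0.0909), a log2 difference of 7.28 (SE 1.27, edgeR adjusted p = 0.0167). Its counts in KO HFD replicates 1, 2 and 3 were 17, 132 and 93. MGP_C57BL6NJ_G0027644 fell in both genotypes and differed by 2.74 (SE 0.42, edgeR adjusted p = 0.0138). MGP_C57BL6NJ_G0017861 rose in both and differed by -6.11 (SE 1.32, edgeR adjusted p = 0.0401), with 1 count over the 3 WT ND libraries and 3 over the 3 KO ND libraries.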

How the results depend on the processing

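The alternatives with the 10 most abundant genes left out, without unannotated loci, with quality weights, without the gene absent from KO and with the first forms of the scores were chosen after seeing the data. None of the 4 printed genes reversed its direction between KO and WT on HFD under any alternative; for other genes only counts were compared. For the gene counts, 69 alternatives stayed within 1.5 times the count reported, 13 gave more and 30 fewer. The 2 correlations moved under 2 of 31 alternatives, and the difference in diet score stayed within the spread of KO HFD under all 6. Of the printed genes' 64 alternatives, 8 ended a call, 7 of them for MGP_C57BL6NJ_G0033860. DESeq2 called 261 genes between genotypes on HFD, 1313 on ND, 656 for the interaction and 632 for the average; the cause was not tested. Without a filter on low counts 71 genes were called on HFD; the cause was not tested. The 6 HFD libraries alone gave 8, with fewer samples to estimate the spread. Quality weights gave 6036 on HFD (3130 higher and 2906 lower), 1997 on ND, 9305 for the diet in KO, 3808 for the interaction and 3499 for the average. Those fits gave KO HFD replicate 3 a weight of 8.80 and WT HFD replicate 3 one of 7.31, against 0.238 for KO HFD replicate 1, so that 1 library per group carried most of the HFD means. A 2-fold minimum left 253 genes on ND, 2483 for the diet in WT, 2646 in KO and 69 for the average, by construction. With 1 replicate left out at a time, which also leaves fewer samples, counts ranged from 7 to 822 on HFD, 92 to 460 on ND, 4380 to 5319 for the diet in WT, 5045 to 6251 in KO, 11 to 942 for the interaction and 62 to 1060 for the average. The correlation of the diet responses ranged from 0.545 (without KO HFD replicate 1) to 0.700, and that of the genotype differences from -0.0215 to 0.0376. The latter was 0.0887 over genes with at least 10 CPM, and the cause of that rise was not tested. It was -0.0387 without the gene absent from KO, so this 1 gene set the sign of the 0.0113 reported. The genotype score difference on HFD was 0.0265 (exact permutation p = 0.2), 0.179 in the first form and 0.0781 in the first form without that gene (exact permutation p = 0.1 for both, the smallest possible). Both changes to the score lowered it. With the replicate number as a block, 47 genes were called on HFD, 892 on ND, 6057 and 6529 for the diet in WT and KO, 198 for the interaction and 320 for the average. The numbers were not taken to pair the libraries, since deviations of same-numbered libraries correlated between -0.0170 and 0.246 and over 0.1 in only 5 of 18 pairs. The median was 0.0552, against -0.0375 for other pairs, 8 of 12 libraries were closest to one of their own number, and the block raised all 6 counts, which is a hint of shared structure from the data and not from the design. Gene list tests and their alternatives were not run for want of symbols, nor was the alternative without mitochondrially encoded genes, of which only the part on the 10 most abundant genes was run. Of genes under 1 CPM 18.3% were called for the diet in WT, against 48.5% over 100 CPM; whether depth sets this was not tested.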

Other observations

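Chosen after their results were seen were the tests of a wrong genotype label, of ND RNA from each genotype, of a lower diet response in KO and of a hidden genotype difference, as well as the reading of KO HFD replicate 1 on calls made without it. Detection breadth and composition also followed the diet. The libraries detected 18259 ± 138 rows in WT ND and 18607 ± 81.5 in KO ND, against 17684 ± 360 in WT HFD and 17927 ± 81.7 in KO HFD (SD, n = 3 each; exact permutation test of the diets, two-sided, p = 0.1 in each genotype, the smallest possible). The 10 most abundant genes of each library took 15.9% ± 0.853 of the counts in WT ND and 22.9% ± 0.638 in WT HFD, and 17.2% ± 0.628 in KO ND and 20.02% ± 2.48 in KO HFD (SD, n = 3 each). Unannotated loci took 2.22% ± 0.109 in WT ND, 2.14% ± 0.0473 in KO ND, 3.27% ± 0.504 in WT HFD and 3.63% ± 0.752 in KO HFD (SD, n = 3 each), and a single such locus, the most abundant, held 1.01% ± 0.0615 in WT ND and 1.92% ± 0.347 in WT HFD. Of the 552 unannotated loci tested, 217 were called for the diet in WT, 39.3% against 41.1% of annotated genes.

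KO HFD replicates 2 and 3 had lower diet scores than replicate 1, with a mean difference of -0.350. Of the 822 genes called between KO and WT on HFD without replicate 1, 814 were also tested with all libraries and had counts in KO, and on these replicate 1 had the same direction as the other two for 56.9%, and its median position was 0.0476 on a scale from the WT HFD mean at 0 to the mean of replicates 2 and 3 at 1. A wrong genotype label of replicate 1 and RNA of a WT ND liver mixed into replicates 2 and 3 are argued against by 0 counts in all 3 of the gene absent from KO, which had at least 2019 in WT, and a few abundant genes by the score gap of -0.349 with the 10 most abundant left out. For RNA of a KO ND liver, mixtures of an HFD and a KO ND library were computed at the observed diet score. In replicate 2 all 12 had higher genotype scores, 0.369 to 0.508 against 0.191 observed, past the 3 SD set (SD 0.0189, of the other HFD libraries). The rule asked this of both replicates together, and replicate 2 was read alone only after the result. Each KO ND source also helped to fit some of the directions that scored its mixtures, which can raise their scores. The values weigh against such mixing into replicate 2 but do not exclude it. In replicate 3 all 12 were also higher, 0.251 to 0.367 against 0.195. The lowest excess, 0.0552, was short of 3 SD, so the rule was not met and mixing into replicate 3 stays open by that limit. Of 9022 genes 28 lay more than 2-fold outside the other 10 libraries in both replicates, against at most 7 for other replicate pairs. That is above the 10 allowed under mixing but under the bound of more than 30 set to exclude it. A lower diet response in KO cannot be told apart from variation between samples, since the diet scores of KO HFD and WT HFD overlapped (exact permutation p = 0.4) and 3 libraries against 3 allow no p under 0.1.

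Fewer genes were called between genotypes on HFD than on ND. The spread brought by KO HFD replicate 1 may account for this, as the HFD count rose to 822 without it and did not exceed 34 without any other HFD library. A smaller genotype difference on HFD cannot be told apart from this: the mean squared log2 difference with noise subtracted was 0.0671 on HFD and 0.158 on ND, a ratio of 0.423, but on HFD it ran from -0.0325 to 0.234 with 1 library left out.

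Most of the genotype difference on ND was not seen on HFD, where 7 of the 666 genes were called in the same direction, all lower in KO, against 0.626 expected of independent lists. An equal difference on HFD hidden by the spread is argued against by the genotype score, which differed between KO and WT by 0.0265 on HFD and by 0.722 on ND. That form scored KO HFD and WT HFD on different directions. In the first form, before its revision, the differences were 0.179 and 0.746. Without the gene absent from KO, the first form gave 0.0781 on HFD (exact permutation p = 0.1, the smallest possible) and 0.722 on ND. A smaller difference on HFD is not excluded by these values. A genotype effect that depends on the diet, and a difference between the groups of ND mice in housing or sampling, remain open as hypotheses and were not tested, since the labels give no cage, litter or day.

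Other splits of the libraries were counted for the comparisons of 3 against 3, where 10 splits are too few for a share under 0.05. The real labels gave the most genes, reached by 1 split of 10 in each: 34 on HFD against 8 for the highest other split, 666 on ND against 1, 5676 for the diet in WT against 1, and 6195 for the diet in KO against 0. A gene with at least 5 counts in one set of 6 libraries and 0 in the other set was found for 1 of the 462 splits of the 12 libraries, the real genotypes, and for 0 genes in every other split, which excludes a chance division.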
